A study of Mus musculus with 6 samples.

How the data were processed

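The authors deposited 1 table of FPKM values for 44065 genes in 6 libraries, with gene names, types, lengths and coordinates. Per the submitters' processing notes, the tools were HISAT2, StringTie and DESeq2, and the genome builds mm10 and mm39; versions and roles are not given in the sources used here. Gene identifiers follow an annotation of the C57BL/6NJ strain, and 2970 loci are unannotated. The table's own build is not settled by these sources, so coordinates are given as the table holds them, with the build open. It holds 0 genes on the Y chromosome. The labels call the 3 samples of a group biological replicates.

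FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values, within a tolerance of 0.001, so whole reads were recovered. Low counts were more often even than odd, as when both mates of a pair are counted, so reads are not independent molecules. Floors are counted in reads, cover no more than counting error, and are not strict bounds because of the pairs. The library totals implied by the deposited values, relative to the summed reads, differed by at most 0.00386% from a median-of-ratios scaling of the recovered reads. Replicates of a group differed by more than sampling noise in every pair, and each counts once.

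Before the data were examined, the main test was set as limma's moderated test with a variance prior that follows expression, on log2(FPKM + 0.5), two-sided, for genes with at least 0.5 FPKM in at least 3 of 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. R 4.3.3 and limma 3.58.1 were used. After the data were seen, limma's voom on the recovered reads with the deposited totals was added as an alternative. Fits without libraries, with a block for the replicate number, with other pseudocounts, filters and scalings, with array weights, and with the GC and length trend of each library removed were also made.

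Of 43 gene lists fixed beforehand, 39 had at least 5 tested members and entered limma's camera with a preset correlation of 0.01. The lists of mitochondrially encoded transcripts, neutrophils, red blood cells and skeletal muscle had 0, 0, 3 and 3 tested members and were not tested. Single values were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3. Named genes were those past the threshold with the 10 largest changes in each direction and non-overlapping groups, filled by p with genes that did not pass, up to 4 members of each list past the threshold, and a fixed panel; the text describes part of them. The same rule was applied to the calls on the reads after the data were seen. Hspa1a of the panel was not matched by name.

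GC content was taken from the longest transcript of each symbol in the GENCODE M21 annotation. Of all tested genes 75.5% had a value and of the genes called on the reads 59.2%, both under 80%, so checks of GC content over those sets as a whole are void. Protein-coding genes had a value in 94.7%, and the calls as a set were checked on these. Named genes and lists were checked in fits over all 14504 tested genes with a value. Their adjusted p after removal of the GC and length trends hold among those genes only.

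The tests were tested on simulated data, with reads drawn for 19201 genes with the libraries' own totals and a dispersion of 0.00555, the median of genes with over 50 read pairs. With 200 genes changed, limma on FPKM recovered 47% of genes changed 1.5-fold and 98% of those changed 2-fold, with 13 false calls among 158; voom recovered 88% and 99%, with 6 false calls among 193. With no gene changed both made 0 calls. These draws held no GC trend. With a GC trend put into the libraries, over 14504 genes with a GC value, voom called 171 of 187 changed genes and made 97 false calls. After removal of the GC and length trends it called 178 of them, with 12 false calls. All these values hold for genes drawn independently, with a dispersion equal in all genes.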

Results

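Total RNA depleted of ribosomal RNA was sequenced from the testes of male C57BL/6 mice that were 6 weeks old when a 10-week exposure began. The files give 3 control and 3 sedentary animals, each with 1 library, called biological replicates in the labels. The design also names a group given physical activity as compensation, which was not analysed here. The series title names sperm DNA damage and testicular temperature control, so the comparison of sedentary with control testes asks which testicular transcripts differ after sedentary housing. Whole reads recovered from the deposited FPKM values came to 37654913, 28495596 and 31432613 in control replicates 1, 2 and 3, and to 34984951, 38148228 and 34176662 in sedentary replicates 1, 2 and 3. Between 27391 and 28627 genes had at least 1 read in a library, and 19201 genes passed the filter on low values.

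In the sedentary testes, markers of Sertoli cells (the somatic nurse cells of the seminiferous tubule) and of elongating spermatids rose as lists, while markers of Leydig cells (the steroid-producing cells between the tubules), of peritubular and smooth muscle cells and of fibroblasts fell as lists. The list of cytosolic ribosomal proteins rose, and lists for steroid synthesis, immediate early genes, double-strand break repair and meiotic recombination fell. These are 10 of 39 lists tested with limma's camera at a preset correlation of 0.01, 3 higher and 7 lower, and all list medians are small, between -0.29 and 0.25 on the log2 scale. With an estimated correlation 0 of the 39 lists passed, and the lowest p was 0.0624, for the circadian clock. With limma's fry 0 lists passed after adjustment and 5 had an unadjusted p under 0.05. At the preset correlation, another division of the 6 libraries into 3 and 3 gave 18 lists. Without control replicate 1, 2 or 3 the test gave 8, 10 and 8 lists, and without sedentary replicate 1, 2 or 3 it gave 9, 4 and 14. With TPM scaling the median log2 fold change of all genes was -0.09 in place of 0.01, and the medians of the Sertoli and elongating spermatid lists were then 0.13 and 0.12, and those of the repair, meiotic, steroid and immediate early lists -0.18, -0.25, -0.17 and -0.22.

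Single genes gave few calls. In the main test, limma on log2(FPKM + 0.5), 5 of 19201 genes passed an adjusted p of 0.05, with 0 higher and 5 lower in the sedentary testes, against 3341 genes with an unadjusted p under 0.05, of which 1947 were higher and 1394 lower. The 3 values of one group all lay above the 3 of the other in 4702 genes, 2623 higher and 2079 lower, or 24.5%. Chance gives 10% on average over the divisions of the libraries. Genes that move together can raise the share in a single division, and the share in the other divisions was not computed. On the recovered reads, limma's voom called 277 genes, 61 higher and 216 lower, of which 2 were also called on FPKM. That fit was chosen after the data were seen. Its calls held 54 protein-coding genes higher and 113 lower, of 13141 tested. Unannotated loci gave 4 calls higher and 83 lower, of 2721 tested. With summed reads in place of the deposited library totals, voom called 429 genes, of which 4.90% were higher, against 22.02% with the deposited totals. Without control replicate 1, 2 or 3, FPKM gave 1, 0 and 2 genes and the reads gave 76, 1058 and 42. Without sedentary replicate 1, 2 or 3, FPKM gave 1, 0 and 0 genes and the reads gave 50, 779 and 22. Most calls on the reads were lower in each of these fits except without sedentary replicate 2, with 418 higher and 361 lower, and sample weights gave 922 higher and 815 lower.

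The 5 genes called on FPKM, each at an adjusted p of 0.0276 by limma, were short or unannotated, and 4 were named only because the count was small, after their values were seen. The snoRNA gene Gm24357 fell from 12.7 ± 0.700 to 5.01 ± 0.896 FPKM (SD, n = 3 per group), on 95 reads in all controls and 39 in all sedentary libraries. An unannotated locus of 815 bases on the plus strand of chromosome 9, from 119940696 to 119941510 in the deposited table (genome build not settled), fell from 7.62 ± 0.162 to 4.11 ± 0.191 FPKM, and the processed pseudogene MGP_C57BL6NJ_G0012114 from 5.27 ± 0.553 to 1.78 ± 0.261 FPKM. Both were also called on the reads, at adjusted p of 0.0183 and 0.0368, and lost that call without control replicate 1 or 3 or sedentary replicate 1 or 3, with adjusted p of up to 0.0768 and 0.165. On FPKM, of the 5 genes 1, Mir7664, was still called without control replicate 3 and 0 without any other library. A pseudogene can share reads with its parent gene, so its value is uncertain. Mir7664 had 9 reads over the controls and the ribosomal RNA model Gm22731 had 10, with 0 in the sedentary libraries. Set against a floor of 3 reads over the group, these are 3.12-fold and 3.47-fold lower. As both mates of a pair are counted and the control reads are taken as exact, these folds are not strict bounds, even for counting error. Without models shorter than 300 bases, FPKM gave 0 genes. Of the 5 genes, 1 was long enough to be tested there, and it lost its call.

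The Sertoli list had all 22 tested members above 0, with a median log2 fold change of 0.25 and an adjusted p of 2.11e-07 by camera. With an estimated correlation its p was 0.109. Amhr2, the receptor for anti-Müllerian hormone, rose on the reads and stood at 72.4 ± 4.91 and 101.3 ± 12.7 FPKM (SD, n = 3), a log2 fold change of 0.48 with an SE of 0.10 and an adjusted p of 0.199 by limma on FPKM and 0.0224 by voom on the reads. Cst9, a cystatin, stood at 138.6 ± 4.77 and 176.4 ± 9.21 FPKM, with an adjusted p of 0.199 on FPKM and 0.0460 on the reads. Both lost the call on the reads without control replicate 1 or 3 or sedentary replicate 1 or 3, with adjusted p of up to 0.113 and 0.185. On the reads of genes with a GC value alone, Amhr2 and Cst9 had adjusted p of 0.0400 and 0.0527, so Cst9 had already lost its call, and after removal of each library's GC and length trend they had 0.0538 and 0.0532. With that removal the log2 fold change of Amhr2 went from 0.48 to 0.33 and that of Cst9 from 0.35 to 0.39. Cst12 and Cldn11, a claudin of the blood-testis barrier, had log2 fold changes of 0.35 and 0.33 and passed in neither fit. Over all genes 0 members passed on FPKM and 2 on the reads, and adjusted over the list alone 9 passed on FPKM and 12 on the reads, all higher. Epididymis markers are a list for neighbouring tissue, and 6 of its 23 members in the data passed the filter on low values. These 6 all lay above 0, with a median of 0.22 and a camera adjusted p of 0.130, and without control replicate 3 the median was 0.10. Whether their reads come from epididymis or from the testis itself was not tested. Their mean log2 level was 2.90 ± 0.0957 in control and 3.12 ± 0.106 in sedentary testes (SD, n = 3, exact permutation p = 0.1, the smallest possible).

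In the elongating spermatid list 15 of 16 members lay above 0, with a median of 0.24 and an adjusted p of 8.77e-04, and p was 0.164 with an estimated correlation. After removal of each library's GC and length trend the median of the list was 0.14 and its adjusted p 0.00599, with p of 0.245 with an estimated correlation. Tnp2, a transition protein that replaces histones in the condensing sperm nucleus, stood at 6583 ± 778 and 8827 ± 834 FPKM, and Prm2, a protamine, at 5049 ± 504 and 6366 ± 167 FPKM. Both rose on the reads, with voom adjusted p of 0.0277 and 0.0389, and missed the threshold on FPKM, at 0.207 and 0.208. Tnp2 lost the call on the reads without control replicate 1 or 3 or sedentary replicate 3, and Prm2 also without sedentary replicate 1, with adjusted p of up to 0.140 and 0.186. With the same removal on the reads the log2 fold changes of Tnp2 and Prm2 went from 0.43 and 0.34 to 0.29 and 0.20, with adjusted p of 0.0783 and 0.181, against 0.0447 and 0.0527 on the reads of the same genes before removal. Prm1 and Tnp1 had log2 fold changes of 0.21 each and passed in neither fit. Prm1 stood at 0.13 without control replicate 1. Under quantile normalization Prm1, Tnp1 and Prm2 came to -0.09, -0.03 and 0.00, and the call of the list ended. That scaling gives genes of equal rank the same value in every library, so it cannot decide on a change of genes this abundant. Over all genes 0 members passed on FPKM and 2 on the reads. Adjusted over the list alone, 4 passed on FPKM, all higher, and 13 on the reads, 12 higher and 1 lower.

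The ribosomal protein list had 55 of 69 members above 0, a median of 0.11 and an adjusted p of 0.00548, and p was 0.279 with an estimated correlation. Its direction by camera turned under quantile normalization, with a median of 0.01, and without sedentary replicate 2 its adjusted p was 0.0704. After removal of each library's GC and length trend its median was 0.07. The call was also lost with TPM scaling, where the median lay just below 0, and, at 0.157, after removal of each library's GC and length trend. Rplp0 stood at 436.8 ± 13.2 in control and 519.7 ± 43.6 FPKM in sedentary testes (SD, n = 3). Over all genes, and adjusted over the list alone, 0 members passed on FPKM or on the reads.

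**Figure D1:**
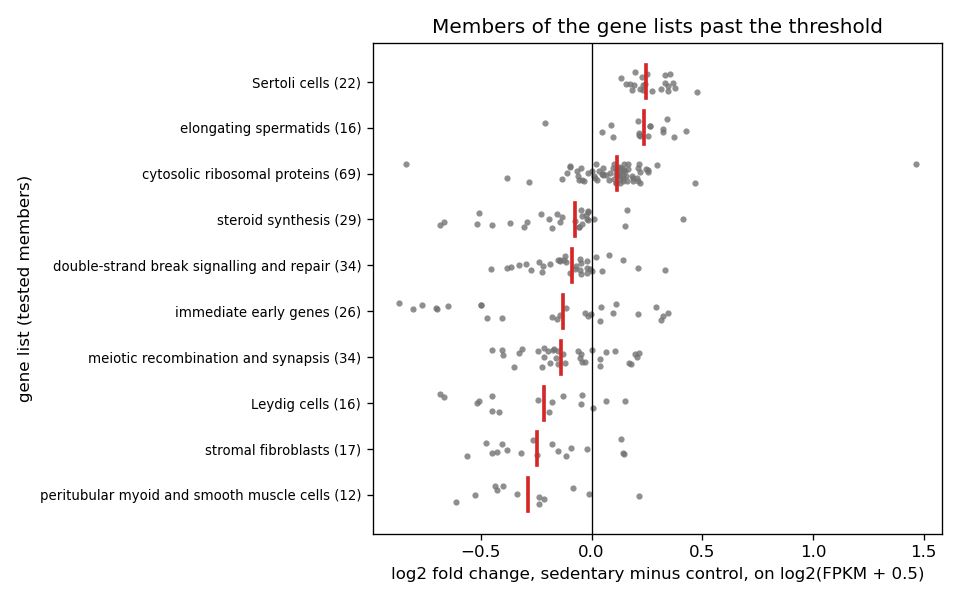
Log2 fold change of each tested member (grey points) of the 10 gene lists past the threshold, with sedentary minus control on the horizontal axis, on the log2(FPKM + 0.5) scale, and 1 row per list, with the number of members in brackets. Red bars are list medians, from -0.29 for peritubular and smooth muscle cells to 0.25 for Sertoli cells; under quantile normalization the ribosomal protein list turned its direction.

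Leydig cell markers had 13 of 16 members below 0, a median of -0.22 and a camera adjusted p of 0.0128, with p of 0.279 with an estimated correlation. The steroid synthesis list, which shares genes with it, had 25 of 29 below 0, a median of -0.07 and an adjusted p of 0.0184, with p of 0.215 with an estimated correlation. Star (MGP_C57BL6NJ_G0033981, chromosome 8 from 24846689 to 24852858, genome build not settled), which moves cholesterol into mitochondria for steroid synthesis, had 10449 reads over the controls and 6573 over the sedentary libraries. It stood at 37.2 ± 9.40 FPKM in control and 22.5 ± 0.359 FPKM in sedentary testes and fell on the reads, with a log2 fold change of -0.70 and a voom adjusted p of 0.0148. It kept that call in 5 of the 6 leave-one-out fits and lost it without sedentary replicate 3 (adjusted p = 0.0849). After removal of each library's GC and length trend it was still called on the reads, with a log2 fold change of -0.67 and a voom adjusted p of 0.0229. Its FPKM adjusted p was 0.199. Hsd3b6, Hsd17b3 and Cyp17a1, steroidogenic enzymes, had log2 fold changes of -0.66, -0.51 and -0.45 and passed in neither fit. Hsd3b6 stood at -0.36 without sedentary replicate 3, Hsd17b3 at -0.31 without control replicate 3, and Cyp17a1 at -0.21 without control replicate 3 and -0.69 without control replicate 2. Without control replicate 3 the Leydig median was -0.07 in place of -0.22. Its call was lost without control replicate 3 (adjusted p = 0.185), sedentary replicate 1 (0.0615) or sedentary replicate 2 (0.0942), and the steroid call without control replicate 3 (0.185) or sedentary replicate 2 (0.187), without a filter or with array weights. The steroid median was -0.12 without control replicate 1 or 2 and -0.15 without sedentary replicate 3, and after removal of each library's GC and length trend it was -0.15 with an adjusted p of 3.49e-04 and p of 0.131 with an estimated correlation. In each of the 2 lists 0 members passed over all genes on FPKM and 1 on the reads, and adjusted over the list alone 1 passed on FPKM; on the reads, 6 Leydig members passed lower, and 7 steroid members lower and 1 higher.

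Peritubular and smooth muscle markers had 11 of 12 members below 0, a median of -0.29 and a camera adjusted p of 0.00452, with p of 0.231 with an estimated correlation. Fibroblast markers had 14 of 17 below 0, a median of -0.25 and an adjusted p of 0.0126, with p of 0.337 with an estimated correlation. Tagln, an actin-binding protein of smooth muscle, stood at 10.9 ± 1.27 and 7.92 ± 1.03 FPKM and passed in neither fit. Pdgfra, a growth factor receptor of stromal cells, stood at 2.50 ± 0.315 and 1.73 ± 0.119 FPKM, and Col3a1, a fibrillar collagen, at 2.00 ± 0.605 and 1.17 ± 0.297 FPKM. Both fell on the reads, with voom adjusted p of 0.0329 and 0.0460. Both lost that call without control replicate 1 or 3 or sedentary replicate 1 or 3, and Col3a1 also without sedentary replicate 2, with adjusted p of up to 0.164 and 0.221. On the reads of genes with a GC value both passed, Pdgfra at 0.0447, and after removal of each library's GC and length trend neither did, at 0.0553 and 0.0613. The log2 fold change of Pdgfra went from -0.53 to -0.46, and that of Col3a1 stayed at -0.77. Without sedentary replicate 2 the muscle and fibroblast lists had adjusted p of 0.0942 and 0.177, and without control replicate 3 the fibroblast list had 0.185 and a median of -0.10 in place of -0.25. TPM scaling also ended the fibroblast call. Over all genes 0 muscle and 0 fibroblast members passed on FPKM, and 0 and 2 on the reads. Adjusted over the list alone, 5 muscle and 0 fibroblast members passed on FPKM, all lower; on the reads 6 muscle members passed lower and 1 higher, and 7 fibroblast members lower.

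Immediate early genes, which cells transcribe within minutes of a stimulus, had 17 of 26 members below 0, a median of -0.13 and a camera adjusted p of 0.0214, with p of 0.321 with an estimated correlation. Fos (MGP_C57BL6NJ_G0020349, chromosome 12 from 88741461 to 88744847, genome build not settled), a transcription factor, had 244 reads over the controls and 85 over the sedentary libraries. It fell on the reads, with a log2 fold change of -1.62 and a voom adjusted p of 0.0172, from 1.04 ± 0.0803 to 0.345 ± 0.129 FPKM. Btg2, Fosl2 and Fosb also fell on the reads, with log2 fold changes of -1.02, -1.21 and -1.07 and voom adjusted p of 0.0193, 0.0216 and 0.0479. Fos lost its call without sedentary replicate 1 (adjusted p = 0.0730), and Btg2 without control replicate 3 or sedentary replicate 1 (up to 0.0730). Fosl2 lost it without control replicate 3 or sedentary replicate 1 or 3 (up to 0.135), and Fosb without any library but control replicate 1 (up to 0.185). On the reads of genes with a GC value, Fos, Btg2 and Fosl2 were still called after removal of the GC and length trends. They had voom adjusted p of 0.0203, 0.0229 and 0.0306 and log2 fold changes of -1.68, -1.04 and -1.22. Fosb missed the threshold on these reads, at 0.0527 before and 0.0526 after removal, with log2 fold changes of -1.07 and -1.18. The list lost its call without control replicate 2 (adjusted p = 0.122) or sedentary replicate 2 (0.317), without a filter, at 1 FPKM, with TPM or quantile scaling, with array weights, and over genes with a GC value (median -0.07). Over these genes, after removal of each library's GC and length trend, its adjusted p was 1.49e-04 and its median -0.18, with p of 0.0587 with an estimated correlation. Without control replicate 3 or sedentary replicate 1 the median was -0.06 and -0.09. Over all genes 0 members passed on FPKM and 7 on the reads, all lower. Adjusted over the list alone, 9 passed lower and 2 higher on FPKM, and 10 lower and 3 higher on the reads.

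**Figure D2:**
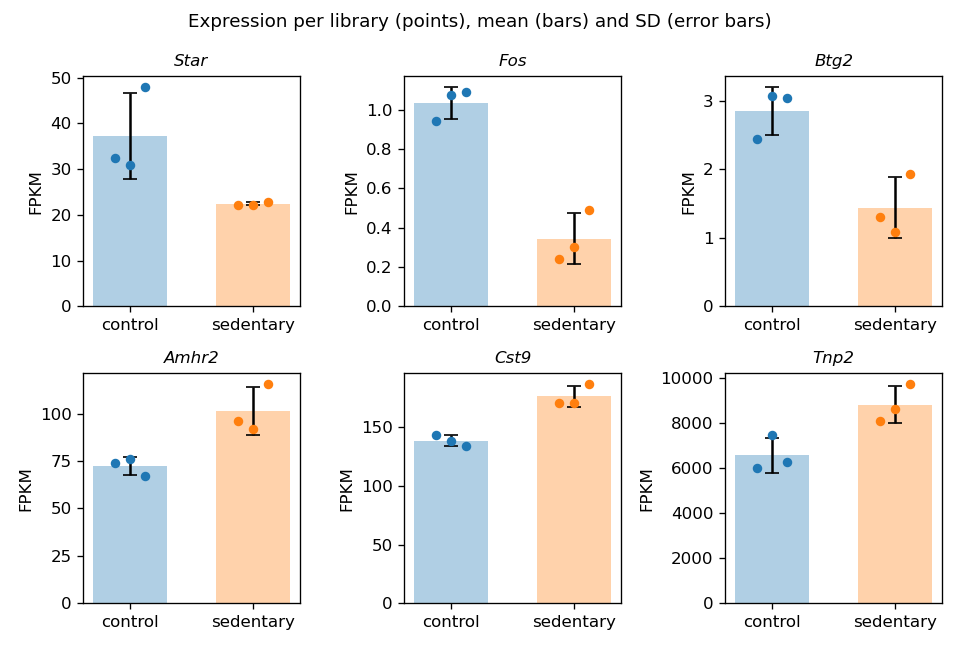
FPKM of Star, Fos, Btg2, Amhr2, Cst9 and Tnp2 in each library, with points for animals, bars for the group mean and error bars for the SD (n = 3), and axes starting at 0. In each panel the values of the groups do not overlap, and none of the 6 genes passed the FPKM fit.

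The double-strand break repair list had 27 of 34 members below 0, a median of -0.09 and a camera adjusted p of 0.00697, with p of 0.108 with an estimated correlation. The meiotic recombination list had 24 of 34 below 0, a median of -0.14 and an adjusted p of 0.0184, with p of 0.189 with an estimated correlation. Rnf168, a ubiquitin ligase at DNA breaks, and Atm, a kinase that responds to them, fell on the reads, with log2 fold changes of -0.40 and -0.65 and voom adjusted p of 0.0433 and 0.0421. Meioc and Sycp2, a meiotic RNA regulator and a component of the synaptonemal complex, fell on the reads by 0.41 and 0.46 on the log2 scale with adjusted p of 0.0368 and 0.0389. These 4 genes lost their calls in 4 of the 6 leave-one-out fits, without control replicate 1 or 3 or sedentary replicate 1 or 3, with adjusted p of up to 0.193, 0.208, 0.165 and 0.192 in that order. On the reads of genes with a GC value all 4 passed, and after removal of each library's GC and length trend none of the 4 did, with log2 fold changes of -0.32, -0.48, -0.25 and -0.26 and adjusted p of 0.0898, 0.0857, 0.109 and 0.111. The medians of the repair and meiotic lists went, with the same removal on FPKM, from -0.09 and -0.14 to -0.0091 and -0.04, with adjusted p of 0.157 and 0.0934, and without control replicate 1 they had 0.0660 and 0.145. The repair median was -0.06 without sedentary replicate 3. Over all genes 0 members passed on FPKM in both lists and 2 on the reads in each, all lower. Adjusted over the list alone 0 passed on FPKM; on the reads, 7 repair members passed lower and 1 higher, and 5 meiotic members lower.

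Genes outside these lists also passed on the reads, and 4 examples were taken from those the naming rule gave. Fxyd2, a regulator of the sodium pump, stood at 13.6 ± 0.720 and 21.5 ± 2.78 FPKM and Sept9, a septin, at 6.65 ± 0.364 and 9.54 ± 0.713 FPKM, and both rose on the reads with voom adjusted p of 0.0280 and 0.0153. Tmem184c stood at 17.2 ± 0.695 and 11.9 ± 0.168 FPKM and P2rx3, an ATP-gated channel, at 14.8 ± 0.527 and 9.91 ± 0.925 FPKM, and both fell with 0.0128. Fxyd2 lost its call without control replicate 1 or 3 or sedentary replicate 1 or 3 (up to 0.117), Sept9 without control or sedentary replicate 3 (up to 0.0779), and Tmem184c and P2rx3 without control or sedentary replicate 1 (up to 0.0504 and 0.0679). After removal of each library's GC and length trend Fxyd2 had an adjusted p of 0.0532 on the reads, against 0.0414 over the same genes before. Its log2 fold change went from 0.65 to 0.55. Sept9, Tmem184c and P2rx3 were still called after the removal, with adjusted p of 0.0229, 0.0306 and 0.0112. Their log2 fold changes were then 0.48, -0.44 and -0.63. Most other named genes outside the lists were not called after the removal. Lrrc25, Defb36, Rfng, Rmnd5b, Pcsk1n, Dact2, Tpbgl, Adap1, Hapln2 and Sac3d1, all higher, had voom adjusted p from 0.0570 to 0.123. Of the lower ones, Adgrg7, Cyp2j6 and Lnpep had 0.0613, 0.0532 and 0.0657, while Zc3h11a and Myt1 were still called, at 0.0479 and 0.0306.

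Genes that answer to heat, cold and oxidative stress did not pass as lists. The inducible heat shock list had a median of -0.01 and a mean of 0.05, with opposite signs, and an adjusted p of 0.465, upward by the test. Of its 19 members 0 passed over all genes on FPKM or on the reads, and adjusted over the list alone 0 passed on FPKM and 3 on the reads, all higher. At an unadjusted p under 0.05 on FPKM, 5 members were higher and 0 lower. After removal of the GC and length trends its median was 0.07. Hspa1b, a heat-inducible chaperone, stood at 5.57 ± 0.815 and 5.42 ± 0.865 FPKM, and Hsph1 at 8.56 ± 0.470 and 7.90 ± 0.672 FPKM. Cirbp and Rbm3, RNA-binding proteins that rise in the cold, stood at 31.1 ± 3.47 and 30.9 ± 2.94 FPKM and at 3.41 ± 0.731 and 3.28 ± 0.287 FPKM. The list of cold-inducible RNA, which also holds temperature-sensing channels, had 5 of its 12 members tested. It had a median of -0.01, a mean of 0.0023 and an adjusted p of 0.903, downward by the test. The antioxidant list had a median of 0.01, a mean of -0.0049 and an adjusted p of 0.869, upward by the test, and Sod1, a superoxide dismutase, stood at 361.9 ± 18.6 and 403.3 ± 16.1 FPKM. The p53 target list had a median of -0.04 and an adjusted p of 0.279, downward by the test. Of its 26 members 0 passed over all genes on FPKM and 2 on the reads, both lower and Btg2 among them, and adjusted over the list alone 1 passed on FPKM and 2 on the reads, all lower. Cdkn1a, a cell cycle inhibitor, had a log2 fold change of 0.38 and an adjusted p of 0.247, and of 0.23 without sedentary replicate 3.

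Libraries also differed in how strongly values followed GC content. Over 12449 protein-coding genes the slope per SD of GC was -0.05, -0.01 and -0.09 on the log2 scale in control replicates 1, 2 and 3, and 0.04, -0.03 and 0.13 in sedentary replicates 1, 2 and 3. The difference between group means had an exact two-sided permutation p of 0.2, where the smallest possible p is 0.1. The first principal component, with 37.0% of the variance, separated the groups. Control replicates 1, 2 and 3 lay at -10.7, -5.45 and -31.7, and sedentary replicates 1, 2 and 3 at 15.0, 8.05 and 24.9.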

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

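All fits on the reads (the block, left-out libraries and sample weights included), the GC corrections, the limit to genes with a GC value and the 300-base limit were chosen after the data were seen; the other settings were set before. The count of 5 genes called on FPKM became 1 without a filter, 3 at 1 FPKM, 2 with a constant variance prior and 16 with array weights. It was 3 over protein-coding genes (0 of them among the 5), 84 at an unadjusted p under 0.05 with a 2-fold change and 22 at an adjusted p under 0.1. Over models of at least 300 bases it was 0. Over genes with a GC value it was 4 (3 of them among the 5), and 0 over the same genes after removal of the GC and length trends. By voom it was 277, and it was 0 to 2 when 1 library was left out. The 277 genes called on the reads became 429 with summed totals, 1737 with sample weights, and 22 to 1058 when 1 library was left out. A refit over the 14504 genes with a GC value gave 125, and from these 125 the count went to 42 after removal of the GC and length trends and 98 after removal of the GC trend; as 59.2% of the 277 have a GC value, the check is void for the 277. The 10 lists became 0 with an estimated correlation, 0 with fry, and 4 to 14 when 1 library was left out. Fewer genes are tested over protein-coding genes, over models of at least 300 bases and over genes with a GC value; otherwise the cause was not tested. Control and sedentary replicates of equal number did not deviate together (correlations of deviations -0.0674, -0.0875 and -0.0346). This cannot show whether animals were paired, and the labels do not say. With the replicate block FPKM gave 0 genes, the reads 381 and the lists 10. DESeq2 and edgeR were not run, as the deposited unit is FPKM; the recovered reads were tested with voom.

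On the reads, the 38 named genes that passed kept their call in 288 refits and lost it in 193, with 0 turned. On FPKM the 81 named genes kept direction and side of the threshold in 1563 of 1668 refits, but all except 5 had not passed to begin with. Lists kept both in 772 of 894. Results that changed direction, mostly near 0, follow as log2 values (medians for lists); by camera a list can turn while its median keeps its sign, and the cause was not tested. Without a filter, the values were -0.0093 for cold-inducible RNA and temperature sensors, 0.00094 for acrosome and fertilization, -0.061 for replication-dependent histones, -0.031 for round spermatids, 0.017 for adipose tissue. With a filter of 1 FPKM, the values were 0.0057 for antioxidant defence, 0.024 for interferon-stimulated genes, -0.021 for replication-dependent histones, -0.049 for endothelial cells. Rescaled to TPM, the values were -0.10 for antioxidant defence, -0.090 for sperm tail and motility, -0.14 for endothelial cells, -0.11 for adipose tissue. Under quantile normalization, Prm2 came to 0, which has no direction. The other values under that scaling were -0.085 for Prm1, -0.034 for Tnp1, -0.041 for inducible heat shock genes, -0.040 for testis-enriched chaperones, -0.034 for antioxidant defence, 0.014 for unfolded protein response, -0.037 for histone-to-protamine transition, -0.11 for sperm tail and motility, 0.012 for cytosolic ribosomal proteins, -0.10 for pachytene spermatocytes, -0.0048 for endothelial cells. With the replicate block, the values were 0.0057 for antioxidant defence. With array weights, the values were 0.050 for Hspa1b, 0.034 for Rbm3, -0.016 for unfolded protein response, 0.0052 for acrosome and fertilization, -0.0059 for differentiating spermatogonia, -0.034 for round spermatids, 0.063 for lymphocytes. Over protein-coding genes, the values were 0.0057 for antioxidant defence, 0.022 for sperm tail and motility, -0.025 for blood-testis barrier. Over genes with a GC value, the values were 0.0057 for antioxidant defence. After removal of the GC and length trends, the values were 0.077 for Rbm3, 0.021 for antioxidant defence, 0.0065 for differentiating spermatogonia, 0.14 for lymphocytes. With 1 library left out, the ranges were -0.12 to 0.085 for Hspa1b, -0.079 to 0.081 for Cirbp, -0.12 to 0.11 for Rbm3, -0.079 to 0.11 for cold-inducible RNA and temperature sensors, -0.0078 to 0.033 for antioxidant defence, 0.00095 to 0.13 for unfolded protein response, -0.013 to 0.066 for sperm tail and motility, -0.032 to 0.035 for acrosome and fertilization, -0.049 to 0.048 for blood-testis barrier, -0.015 to 0.18 for differentiating spermatogonia, -0.14 to 0.039 for round spermatids, -0.13 to 0.016 for endothelial cells, -0.090 to 0.37 for macrophages, -0.080 to 0.16 for lymphocytes, -0.031 to 0.097 for adipose tissue. The sperm tail list became called under quantile normalization, with an adjusted p of 0.0111. Depth limits the short models, as small RNA genes had a median of 3.50 reads per library.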

Other observations

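The tests of GC slopes and of GC and length trends behind the gene and list calls, the test of other interstitial cell types, the single-gene counts in other divisions of the libraries, and the comparison of small RNA genes alone inside and outside genes, were chosen after the result was seen. The lists given next did not pass at the preset correlation. By limma's camera, adjusted p was 0.0631 for the circadian clock (median log2 fold change -0.09), 0.0880 for glucocorticoid-responsive genes (-0.09), 0.122 for inflammatory cytokines (-0.11) and 0.130 for epididymis markers (0.22, 6 of 6 tested members above 0, of 23 in the data). It was 0.235 for testis-enriched chaperones, 0.279 for base and nucleotide excision repair, 0.279 for apoptosis machinery, 0.414 for leptotene to zygotene spermatocytes, 0.414 for hypoxia response, 0.420 for macrophages, 0.432 for undifferentiated spermatogonia, 0.432 for interferon-stimulated genes and 0.480 for replication-dependent histones. It was 0.538 for pachytene spermatocytes, 0.609 for the histone-to-protamine transition, 0.668 for the piRNA pathway, 0.781 for differentiating spermatogonia, 0.781 for the unfolded protein response and 0.851 for sperm tail and motility. The acrosome, endothelial, round spermatid, blood-testis barrier, adipose and lymphocyte lists each had 0.869. Signs differed within 3 of them. The acrosome list had a median of 0.00094 and a mean of -0.01, downward by the test, the endothelial list a median of -0.05 and a mean of 0.01, downward, and the blood-testis barrier list a median of -0.02 and a mean of 0.02, upward. After removal of the GC and length trends the circadian and glucocorticoid lists had adjusted p of 0.00244 and 0.00205 at the preset correlation. With an estimated correlation p was then 0.0197 and 0.102, and adjusted p 0.719 for each. Of the members of these lists 0 passed over all genes on FPKM. On the reads 2 histone-to-protamine members passed higher and 1 lower, 2 sperm tail members lower, 1 blood-testis barrier member higher, 1 member lower in each of the piRNA, apoptosis, glucocorticoid, leptotene and adipose lists, and 0 in the others. Adjusted over the list alone on FPKM, 5 members of the histone-to-protamine list passed higher and 2 lower, 2 pachytene members higher, 1 apoptosis and 1 undifferentiated spermatogonia member higher, 1 glucocorticoid and 1 leptotene member lower, 1 histone and 1 adipose member each way, and 0 in the others.

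In the first pattern, the calls on single genes, FPKM gave 5 genes and the reads 277 with the real groups, and among the other 9 divisions of the 6 libraries the highest were 0 and 1; 1 of 10 divisions gave as many in each case, and 10 divisions are too few for a share under 0.05. The gap between the group means of the GC slopes was 0.622 of the largest range within a group and sedentary replicate 2 lay below control replicate 2, as library-to-library GC bias would give. Of 167 called protein-coding genes 155 have a GC value, and a refit over protein-coding genes with a value called 77, 16 of them higher; after removal of the GC and length trends 28.6% of the 77 were still called, all 77 kept their sign, and 2 of the 29 genes then called were higher. The median absolute log2 fold change of the 77 went from 0.57 to 0.45 and their median SE from 0.116 to 0.0946, a median ratio of 4.59 before and 4.43 after, while the largest unadjusted p that passes went from 3.03e-04 to 1.09e-04, and 34 of the 77 lay under the earlier limit after removal, so calls ended both through a smaller ratio and through the stricter limit. These trends may account for part of the calls, and whether they are the whole cause cannot be told apart from the group at this number of libraries.

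The second pattern is the lists of cell type markers. Of the 10 divisions of the libraries, 4 gave at least as many lists as the real groups, with 18 the highest of the others against 10, and 10 divisions are too few for a share under 0.05. Removal of the GC and length trends left medians of 0.20, -0.29, -0.29 and -0.35 for the Sertoli, Leydig, fibroblast and muscle lists. They were 0.25, -0.22, -0.25 and -0.29 before, which argues against these trends as the whole cause of these 4 medians. After removal the highest camera adjusted p of the 4 was 5.39e-04 at the preset correlation. Some other divisions passed as many lists by that measure, so it cannot tell the group from other differences between libraries. With an estimated correlation p was 0.117, 0.207, 0.244 and 0.102, and adjusted p 0.719 for each. The repair, meiotic and ribosomal lists lost their call at the preset correlation with the same removal. Less interstitial tissue of every kind stays open. Macrophage and endothelial markers lay above the 3 falling lists by 3.19 and 2.33 SDs between libraries (exact permutation p = 0.1 each, the smallest possible). With the mean of members they lay above by 1.79 and 1.69 SDs. Endothelial markers lay above by 1.89 SDs without sedentary replicate 3, where their median fold change was -0.13. The macrophage median was -0.09 without control replicate 2. Without control replicate 3 it was 0.37, with a camera adjusted p of 2.91e-05 at the preset correlation and a distance of 6.94 SDs. The 8 endothelial members are low, with a median log2 level of 0.80. The 3 falling lists were chosen because they fell in this same comparison. A list not chosen for falling tends to lie above them for that reason alone, so these distances cannot decide. A change in the makeup of the testis with sedentary housing stays open as a hypothesis, as does an uneven sampling of the tissue. The 6 tested epididymis markers, of 23 in the data, were higher in each sedentary library (3.01, 3.12 and 3.22 as mean log2 level) than in each control (2.90, 2.99 and 2.80). As the other members fell below the filter, these 6 cannot decide on uneven sampling.

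In the third pattern, a shift of short and unannotated genes, small RNA genes had a median log2 fold change of -0.30 over 336 genes with a GC value, while their share of reads, 0.0319 ± 0.00134% in control and 0.0305 ± 0.000814% in sedentary libraries, overlapped between groups (exact permutation p = 0.2); unannotated loci had a median of -0.03 and took 2.10 ± 0.0345% of reads in control and 1.99 ± 0.0308% in sedentary libraries (exact permutation p = 0.1, the smallest possible). On the reads voom called 4 unannotated loci higher and 83 lower, of 2721 tested. After removal of the GC trend the small RNA median was -0.26, with a bootstrap 95% interval from -0.32 to -0.17, which does not decide on shared GC content against the bound of -0.2 set beforehand. Less unspliced host RNA may lower loci inside genes, but small RNA genes inside annotated genes differed from those outside by 0.0027 (permutation p = 1), and 0 of 2721 unannotated loci lay inside an annotated gene on the same strand, so the test has no value for them. Over both classes together the difference was -0.26 (permutation p = 1e-05, the smallest possible), because the loci inside genes were all small RNA genes. The biological explanation that the groups give stays untested.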
